A study of Mus musculus with 19 samples.

How the data were processed

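Lung RNA of 19 adult male MutaMouse animals, a transgenic strain that carries a reporter for scoring mutations, was measured on 2-colour Agilent arrays. The mice were 25 weeks old and had been gavaged daily for 28 days, and part of the lung was taken 3 days after the last dose. Groups were taken from the labels: 5 vehicle controls, 5 mice at 25 mg/kg/day of benzo(a)pyrene (BaP, a polycyclic aromatic hydrocarbon formed in combustion), 4 mice at 50 mg/kg/day and 5 mice at 75 mg/kg/day. The design text gives 5 mice per group, and 4 arrays at 50 mg/kg/day were analysed here. Each mouse had its own number in the labels and its own array, so no samples were paired. On every array the lung RNA carried Cy5 and a commercial reference pooled from mouse cell lines carried Cy3, per the labels, with no dye swap, so a dye effect of single probes is shared by all groups.

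Spot intensities were deposited as the scanner output of Feature Extraction 10.7.3.1, per the file headers, for 45018 spots per array, of which 43379 were not controls. The intensity columns used were the median brightness of each spot and of its local background in both channels. The design as first written had assumed mean spot intensities, and the median columns were used in their place. Feature Extraction's processed intensities, per the file headers background-subtracted and dye-normalized, were kept for an alternative. The table deposited by the authors holds a log2 ratio of lung over reference per spot. Its scale and direction were found by setting each column against ratios of that array after loess without background subtraction, where r was 0.995 to 0.998 and the slope 0.991 to 0.995. Its column medians lay between -0.053 and -0.033 on the log2 scale, and how the authors centred it is not given in the sources used here.

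Background was corrected with normexp and an offset of 50 in limma 3.58.1 under R 4.3.3, and each array was normalized by loess with control spots at weight 0. The offset compresses the folds of dim spots, so a fold given for a dim gene understates its change. Spots marked as outliers in either channel (0.29%) were left out, and 0 spots were saturated. Spots of a probe were averaged. Of the 41174 probes, 23374 (56.77%) were named through a table of mouse RefSeq genes of assembly GRCm38.p6 by accession without version, which gave 16535 symbols, and the others kept the accession of the array design. Probes well above background in the lung channel on at least 4 arrays were kept (24501). A gene was represented by its probe with the highest mean lung intensity, which left 19315 genes, 12324 with a symbol and 6991 under an accession, with 22 missing values. Of the named genes with several probes past the filter, Aif1 and Per2 had probes that went opposite ways at 75 mg/kg/day, and some others, such as Ces2e, had probes with much smaller differences than the probe used.

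Between 45.59% and 62.89% of the spots (19777 to 27279) were well above background in the lung channel, and between 24601 and 30954 spots in the reference channel. The median lung intensity above local background was 11.7 to 36.6 units per array, and these values together with the number of arrays limit the precision. Feature Extraction's own quality report marked 4 arrays for evaluation: controls 1 and 3, mouse 12 at 50 mg/kg/day and mouse 20 at 75 mg/kg/day. The arrays lay on 6 slides scanned on 5 days, and every slide held more than 1 group. Principal component 1 of the ratios (21.9% of the variance) had an r2 of 0.763 with slide and 0.122 with dose group, component 2 (17.6%) 0.643 and 0.351, and component 3 (12.2%) 0.36 and 0.62.

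The log2 ratios of all 19 arrays were fitted together with a mean per group in limma (lmFit and eBayes), and each dose was compared with the controls and with the other doses. A second fit took dose as a number over all arrays, and a further fit did so over the 14 treated arrays. Values of p were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Slide was not part of these fits and was tried as a block. Within slides, a difference was checked on the 4 slides that held a control and a mouse at 25 mg/kg/day, the 3 with a control and 50 mg/kg/day, and the 4 with a control and 75 mg/kg/day. Before the data were examined, 35 lists of pathway genes and cell type markers were written, and 34 had at least 5 genes tested. They were tested with camera at a preset correlation of 0.01, two-sided, with adjustment over the lists, and beside it with an estimated correlation and with fry. Lists share few members, at most 3, which DNA repair shares with p53 targets. A list score per mouse is the mean log2 ratio of its genes minus the control mean. All exact permutation tests of scores are two-sided. With 5 mice against 5, and with 4 against 5, the smallest p they can give is 0.0079.

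The named genes were fixed by a rule: per dose, the 10 largest rises and the 10 largest falls among genes past the threshold for which every treated mouse lay on that side of the control mean, genes with a symbol only. The rule added the 4 members with the smallest trend p of every list called in any comparison, and in any case Cyp1a1, Cyp1b1, Nqo1, Cdkn1a and Cd79a. Some genes under this rule are not reported here, and they stay in the fits, the counts and the lists. Genes named outside the rule were chosen after their values were seen, and the text says so. Errors of log2 differences are standard errors from limma, and intervals of folds are at 95%.

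The reference channel, brought to one intensity distribution over arrays after loess (Aquantile), served as a negative control, since the same reference RNA went on every array. Because the comparisons share the same 5 controls, agreement between doses was set beside 100 simulations of unchanged groups and beside controls divided into 2 and 3 mice. The alternatives covered background correction, normalization, the lung channel alone, the deposited ratios, the filter on dim probes, the choice of probe, the variance model, slide and scan day, the threshold and each array left out in turn. Further ones were added after the data were seen: the fit without the 4 arrays marked for evaluation, the fit with muscle and fat marker scores as covariates, and exact permutation tests of list scores.

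The fit was tested on simulated arrays with the real spread of 19293 genes, in which 67 genes were changed by 1.5-fold, 67 by 2-fold and 66 by 4-fold. At 25 mg/kg/day it called 73.1%, 94% and 98.5% of them, at 50 mg/kg/day 67.2%, 92.5% and 100%, at 75 mg/kg/day 74.6%, 97% and 100%, and for the trend 74.6%, 97% and 100%. It also called 19, 14, 12 and 9 unchanged genes, in that order, which at each of the 3 doses is a larger share of its calls than the threshold aims at. Of 20 simulated lists of 20 genes at 75 mg/kg/day, all 5 shifted by 1.5-fold were called and 0 of the others. The simulated genes varied independently of each other and carried no slide effect. The result therefore does not show how often camera calls unshifted lists in the real arrays, where members of a list vary together. Figures were drawn with matplotlib 3.10.9.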

Results

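The series asked how oral benzo(a)pyrene (BaP) changes gene expression in the lung of the MutaMouse over a range of 3 doses. Part of the lung was taken 3 days after the last dose. Its RNA was measured in 5 control mice, 5 mice at 25 mg/kg/day, 4 mice at 50 mg/kg/day and 5 mice at 75 mg/kg/day. Each mouse had an array of its own against a common reference. Between 19777 and 27279 spots per array were well above background in the lung channel. The number of changed genes was larger at each higher dose: 10 of the 19315 genes tested passed the threshold at 25 mg/kg/day, 211 at 50 mg/kg/day and 807 at 75 mg/kg/day. Targets of p53, the transcription factor activated by DNA damage, were among the genes that rose most, and as a group they were higher at all 3 doses. Cyp1a1, the enzyme that is the usual marker of exposure to BaP through the aryl hydrocarbon receptor (AhR), did not pass the threshold at any dose.

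**Figure D1:**
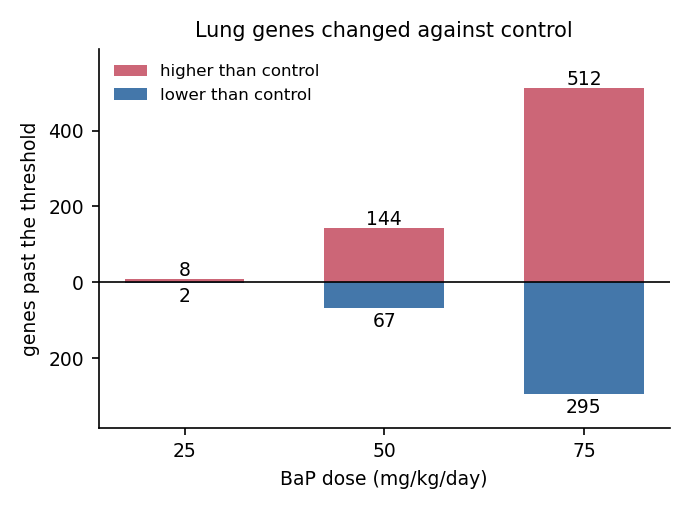
Number of lung genes past an adjusted p of 0.05 against control (y axis) at each BaP dose in mg/kg/day (x axis), with genes higher than control above the line and genes lower than control below it. The counts go from 8 higher and 2 lower at 25 mg/kg/day to 512 higher and 295 lower at 75 mg/kg/day.

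At 25 mg/kg/day, 8 genes rose and 2 fell. Cdkn1a, which encodes the p21 inhibitor of the cell cycle, rose 2.57-fold (95% interval 1.85 to 3.56, n = 5 against 5, limma adjusted p = 0.024). Gdf15, a secreted stress cytokine, rose 2.43-fold (1.83 to 3.24, adjusted p = 0.015), and Phlda3, a p53 target that restrains Akt, rose 2.02-fold (1.59 to 2.57). Ephx1, the epoxide hydrolase that takes part in BaP metabolism, rose 1.72-fold, Trp53inp1 1.68-fold, the apoptosis gene Bax 1.49-fold and Ei24 1.46-fold. The falls were Matn2, a matrix protein, by 0.58 ± 0.10 (SE) on the log2 scale, and Ephb2, an ephrin receptor, by 0.48 ± 0.08. These 9 genes lay on the same side of the control mean in 5 of 5 mice, which the naming rule required. They differed in that direction on 4 of 4 slides that held both groups. The tenth called gene had no symbol. At an unadjusted p under 0.05 there were 1512 genes, against 966 by chance. The count is fragile: it was 3 without mouse 7 or without mouse 8 of this dose, 5 without control 2 or 3, 4 without control 4, and 0 with median centring in place of loess, which moved the median of all genes to 0.148 on the log2 scale. With slide as a block Gdf15 (1.26, adjusted p = 0.055) and Bax (0.55, adjusted p = 0.055) missed the threshold and Ces2e passed it (1.08, adjusted p = 0.033). Cdkn1a kept its call at this dose in 24 of 39 alternatives and was between 1.22 and 1.56 higher in all of them. Matn2 kept its call in 15 of 39 and Ephb2 in 17 of 38, with differences of -0.64 to -0.31 and -0.81 to -0.26.

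At 50 mg/kg/day, 144 genes rose and 67 fell. Gdf15 rose 6.59-fold (95% interval 4.86 to 8.94, n = 4 against 5, adjusted p = 1.1e-06), Cdkn1a 6.07-fold (4.29 to 8.58, adjusted p = 6.8e-06) and Ces2e, a carboxylesterase, 5.82-fold (4.1 to 8.26). The Ces2e spot was well above background in 2 of 5 controls, so this fold is set against a dim group. Ccdc184 rose 3.95-fold, Ccng1 (cyclin G1, a p53 target) 3.48-fold, Phlda3 3.44-fold, Mmrn2, an endothelial matrix protein, 3.29-fold, Trp53inp1 2.64-fold, Thyn1 2.58-fold and Aen, a nuclease induced in apoptosis, 2.5-fold. Among the falls, Grp, the gastrin-releasing peptide, fell by 1.22 ± 0.29 on the log2 scale, with its spot well above background on 2 of 4 arrays, Tmeff2 by 1.11 ± 0.25, Rpl22l1 by 0.88 ± 0.11, the carbonic anhydrase Car14 by 0.79 ± 0.19 and the acyl-CoA thioesterase Acot1 by 0.76 ± 0.17. The ribosomal protein genes Rps27, Rps13 and Rpl13 fell by 0.67 ± 0.11, 0.66 ± 0.15 and 0.64 ± 0.09, and Cpne5 and Rasa4 each fell by 0.63, with standard errors of 0.15 and 0.10. With median centring Rps27, Rps13 and Rpl13 were at -0.27, -0.27 and -0.23 at this dose, and Rps27 and Rpl13 at 0.37 and 0.26 at 75 mg/kg/day. Ribosomal protein genes, a list added after their falls were seen, had a median of -0.34 in the ratio and 0.12 in the reference channel at 50 mg/kg/day. The named falls and rises held in 4 of 4 mice, which the naming rule required, and on 3 of 3 slides. Over the alternatives the calls of Car14, Grp and Rps13 at this dose held in 13 of 39, 16 of 37 and 18 of 39. Those of the other named falls held in 21 of 39 or more. The number of called genes was 77 without mouse 15 of this dose, 116 without mouse 12, 132 without mouse 13, 98 without control 2 and 122 without control 4. It was 413 with slide as a block, and with median centring, which moved the median of all genes to 0.137, it was 9, all higher.

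At 75 mg/kg/day, 512 genes rose and 295 fell, and 189 of the rises and 82 of the falls were at least 1.5-fold. Cdkn1a rose 9.68-fold (95% interval 6.98 to 13.4, n = 5 against 5, adjusted p = 3.4e-08), Gdf15 8.95-fold (6.72 to 11.9, adjusted p = 2e-08) and Ces2e 8.05-fold (5.79 to 11.2, adjusted p = 1.3e-07). Another Ces2e probe was 0.24 higher on the log2 scale, against 3.01 for the probe used. Over the alternatives the Ces2e difference at this dose ranged from 1.63 to 4.69 and is set against dim controls, so its fold is not precise. Aen, Cpne5 and Igfbp5 also had a probe with a smaller difference at this dose (0.27, -0.16 and -0.33), and Psrc1 had a pair of them (0.81 and 0.47). Ccdc184 rose 5.56-fold, Mmrn2 5.16-fold, Ccng1 4.92-fold, Phlda3 4.3-fold, Psrc1, a spindle protein gene and p53 target, 3.42-fold, Thyn1 3.39-fold and Lyve1, the hyaluronan receptor of lymphatic endothelium, 3.25-fold. The deepest falls were in Gpihbp1, which anchors lipoprotein lipase on capillary endothelium (by 1.42 ± 0.19 on the log2 scale), the endothelin receptor gene Ednrb (by 1.24 ± 0.22) and Galnt15 and Car14 (each by 1.22, standard errors 0.16 and 0.18). Tmeff2 fell by 1.11 ± 0.23, Grp by 1.10 ± 0.27, Rpl22l1 by 1.05 ± 0.10, Igfbp5 by 1.01 ± 0.21, the mitochondrial leucyl-tRNA synthetase gene Lars2 by 0.98 ± 0.22 and Igfbp6 by 0.94 ± 0.12. All of these held in 5 of 5 mice, which the naming rule required, and on 4 of 4 slides. The number of called genes was 454 without mouse 18, 462 without mouse 16 and 533 without control 2. It was 1776 with slide as a block, and with median centring it was 535, of which 532 were higher and 3 lower, while the median of all genes moved to 0.351 on the log2 scale and Lars2 to 0.12.

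**Figure D2:**
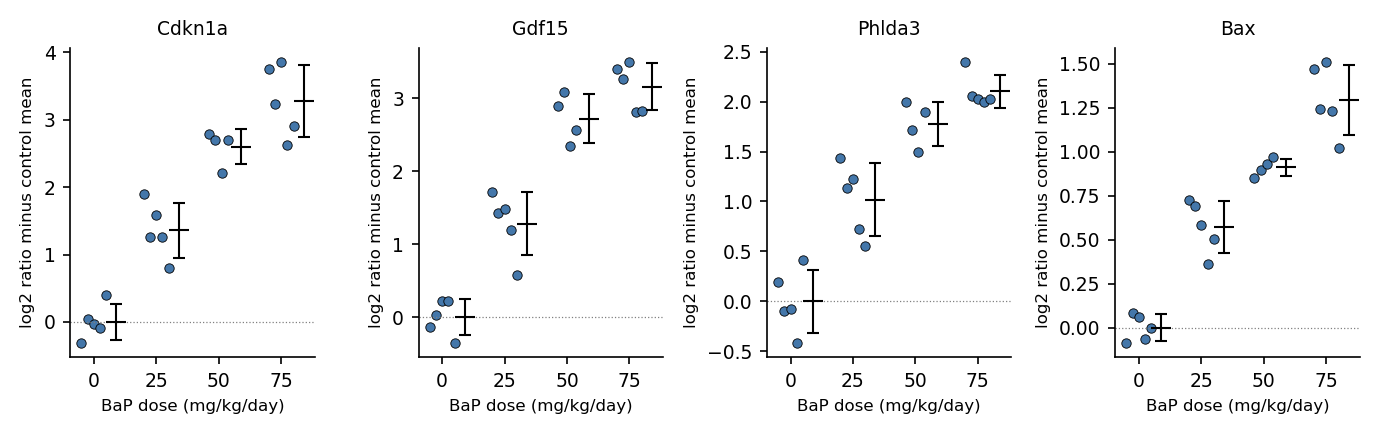
Log2 lung/reference ratio minus the control mean (y axis) of Cdkn1a, Gdf15, Phlda3 and Bax against BaP dose in mg/kg/day (x axis). Each point is a mouse, and the bar beside each group gives the mean and SD (n = 5, 5, 4 and 5). The mean folds of Cdkn1a were 2.57 at 25 mg/kg/day, 6.07 at 50 mg/kg/day and 9.68 at 75 mg/kg/day.

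Targets of p53 were higher as a group at every dose, although not every member passed the threshold or was higher. Of the 28 members tested, 6 rose at 25 mg/kg/day, 12 at 50 mg/kg/day and 16 at 75 mg/kg/day. Adjusted over the list alone 11, 17 and 22 rose, and 0, 0 and 2 fell. The mean score of the list was 0.31 ± 0.08 (SD, n = 5), 0.67 ± 0.10 (n = 4) and 0.91 ± 0.15 (n = 5), against 0 ± 0.12 in the controls, on the log2 scale. Camera's adjusted p was 7.95e-13, 3.78e-24 and 3.91e-29, and with an estimated correlation the adjusted p was 0.0337, 0.00171 and 0.000623. The score was above the control mean in all 14 treated mice and higher than the control of the same slide on 4 of 4, 3 of 3 and 4 of 4 slides. With slide as a block camera's adjusted p was 4.77e-11, 4.69e-19 and 1.46e-23. An exact permutation test of the scores gave p = 0.016, 0.0079 and 0.0079, and adjusted over the 34 lists 0.18, 0.13 and 0.13, where a single list at the smallest p these group sizes allow cannot pass. Members picked after their values were seen include Mdm2, the ubiquitin ligase that degrades p53, which rose by 0.79 at 50 mg/kg/day and 1.12 at 75 mg/kg/day on the log2 scale. Sesn2 rose by 1.40 at 75 mg/kg/day and Polk, a DNA polymerase that bypasses bulky adducts, by 0.85, whereas Sesn1 fell by 0.43 at 75 mg/kg/day (adjusted p = 0.019). At 75 mg/kg/day Ddb2 (-0.11), Xpc (0.15), Gadd45a (0.15) and Rrm2b (0.06) did not pass the threshold.

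Gdf15, Ces2e and Cdkn1a also differed between treated groups. Between 25 and 50 mg/kg/day 2 genes passed, Gdf15 (1.44 higher on the log2 scale, adjusted p = 0.031) and Ces2e (adjusted p = 0.038), and 748 had an unadjusted p under 0.05, against 966 by chance. The count was 1 with slide as a block and 0 without the dim-probe filter, and in 16 of the 19 runs without 1 mouse it moved to 0, 1 or 4. Between 50 and 75 mg/kg/day limma called 0 genes (946 at an unadjusted p under 0.05, against 966 by chance), also with slide as a block. Between 25 and 75 mg/kg/day 75 genes were higher and 35 lower, with Cdkn1a higher by 1.92 ± 0.23 (adjusted p = 0.00032). This count was 49 without mouse 16 and 50 without mouse 18 at 75 mg/kg/day, 55 without mouse 10 and 60 without mouse 8 at 25 mg/kg/day, and 293 with slide as a block. A linear trend over all doses passed in 900 genes, 544 rising and 356 falling. Over the treated mice alone the trend passed in 113, of which 76 rose, and 103 of these were among the 900. The count over all mice was 589 without mouse 16 at 75 mg/kg/day. The count over treated mice was 56 without that mouse, 51 without mouse 18, and 71, 74 and 59 without mice 7, 8 and 10 at 25 mg/kg/day. With slide as a block the counts were 1745 and 309. In comparisons that share the controls, all 10 genes called at 25 mg/kg/day were called in the same direction at both higher doses, and 187 of the 211 called at 50 mg/kg/day were called in the same direction at 75 mg/kg/day.

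Over all genes, log2 differences from control correlated across genes at r = 0.657 between 25 and 50 mg/kg/day, 0.759 between 25 and 75 mg/kg/day and 0.76 between 50 and 75 mg/kg/day, and genes are not independent replicates. The doses share their controls, and unchanged groups simulated against those controls gave a mean r of 0.473, 0.475 and 0.452. In 14, 2 and 2 of 100 simulations r was at least as high as observed. The covariance was 0.0268, 0.0364 and 0.0391, against 0.0127, 0.0119 and 0.012 in the simulations. With the controls divided between the 2 doses compared, the median r was 0.173, 0.296 and 0.305.

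AhR target genes showed no group change past the threshold in lung taken 3 days after the last dose, and these arrays hold no earlier time. Cyp1a1 differed from control by -0.86 ± 0.95 at 25 mg/kg/day, -0.88 ± 1.01 at 50 mg/kg/day and 0.24 ± 0.95 at 75 mg/kg/day on the log2 scale. Cyp1b1, another cytochrome P450 of this pathway, differed by 0.09 ± 0.43, 0.15 ± 0.46 and 0.84 ± 0.43, and Nqo1, a quinone reductase, by -0.10 ± 0.26, 0.07 ± 0.27 and 0.14 ± 0.26. The adjusted p of these 3 genes was 0.33 or more at each dose. Cyp1a1 was below the control mean in 5 of 5 mice at 25 mg/kg/day and 4 of 4 at 50 mg/kg/day, and below the control of the same slide on 4 of 4 and 3 of 3 slides. The errors come from a variance pooled over the groups, with an SD of 0.41 and 0.29 at these doses and 3.14 at 75 mg/kg/day. A single mouse set the value at 75 mg/kg/day and most of that variance: the log2 ratio was 7.3 in mouse 20 and between 0.13 and 0.45 in the other 4 mice of that dose. Without mouse 20 the difference of Cyp1a1 from control was -1.16 on the log2 scale, with an adjusted p of 0.023. Of the 14 tested members of the AhR battery list 0 passed at any dose, and camera's adjusted p for the list was 0.277, 0.448 and 0.438.

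**Figure D3:**
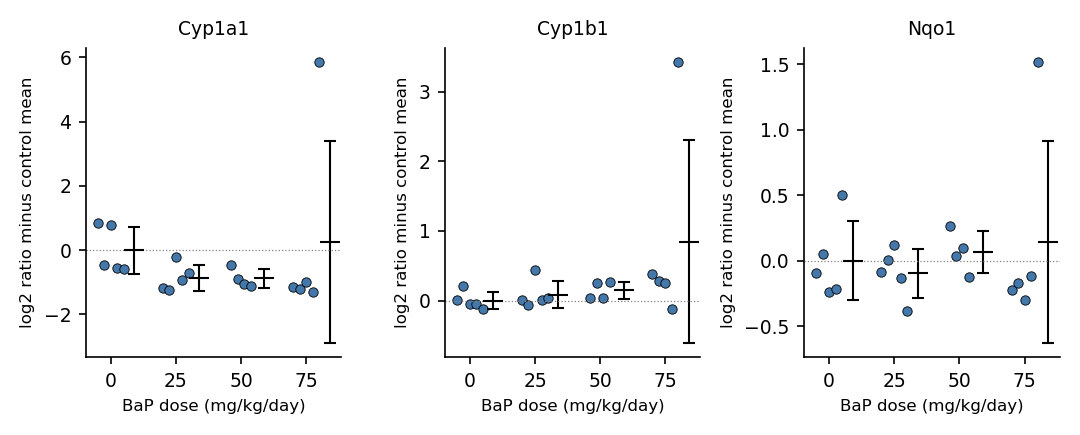
Log2 lung/reference ratio minus the control mean (y axis) of Cyp1a1, Cyp1b1 and Nqo1 against BaP dose in mg/kg/day (x axis). Each point is a mouse and the bar beside each group gives the mean and SD (n = 5, 5, 4 and 5). Mouse 20 at 75 mg/kg/day stands apart from the other mice of its dose in all 3 genes.

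Markers of B cells and NK cells were lower at 50 and 75 mg/kg/day by camera with its preset correlation. Of 25 tested B cell markers 0 passed alone at 25 or 50 mg/kg/day and 3 fell at 75 mg/kg/day: Cd79b, part of the B cell receptor, by 0.62 ± 0.15, the signalling adaptor Blnk by 0.59 ± 0.14 and the BAFF receptor gene Tnfrsf13c by 0.46 ± 0.12. With median centring, where all genes had a median of 0.351 at this dose, Cd79b and Blnk were at 0.11 and 0.18, still below that median. Cd79a was at 0.03 ± 0.09 at 75 mg/kg/day. The adjusted p of the list was 3.82e-06 at 50 mg/kg/day and 0.000497 at 75 mg/kg/day, and with an estimated correlation the adjusted p was 0.727 and 0.729. The B cell score was below the control mean in 4 of 4 mice at 50 mg/kg/day (-0.26) and 5 of 5 at 75 mg/kg/day (-0.24), but below the control of the same slide on 2 of 3 and 3 of 4 slides, and an exact permutation test gave p = 0.087 and 0.071. Adjusted over the list alone, 9 B cell markers were lower at 50 mg/kg/day and 5 at 75 mg/kg/day. NK cell markers were lower at 50 mg/kg/day (adjusted p = 0.00121) and 75 mg/kg/day (1.69e-05), where Klrb1c, the NK1.1 receptor, fell by 0.52 ± 0.12, with its spot well above background on 1 of 5 arrays at that dose, and Ccl5 was at -1.01 ± 0.29 (adjusted p = 0.055). With an estimated correlation the adjusted p of the list was 0.772 and 0.729. T cell markers were lower at 75 mg/kg/day (adjusted p = 0.0398, and 0.729 with an estimated correlation), with 0 of 20 members past the threshold and Cd5 at -0.44 ± 0.14. The T cell call ended with slide as a block (0.0511) and without control 3, control 4, mouse 18 or mouse 20, with an adjusted p of up to 0.0678. The NK cell score was below the control mean in 3 of 4 mice and on 2 of 3 slides at 50 mg/kg/day (-0.32, exact permutation p = 0.13), and in 5 of 5 mice and on 3 of 4 slides at 75 mg/kg/day (-0.45, exact permutation p = 0.024). The T cell score at 75 mg/kg/day was below it in 5 of 5 mice and on 4 of 4 slides (-0.14, exact permutation p = 0.032). In the trend with dose, fry called NK cells beside the p53 targets (adjusted p = 0.0244).

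**Figure D4:**
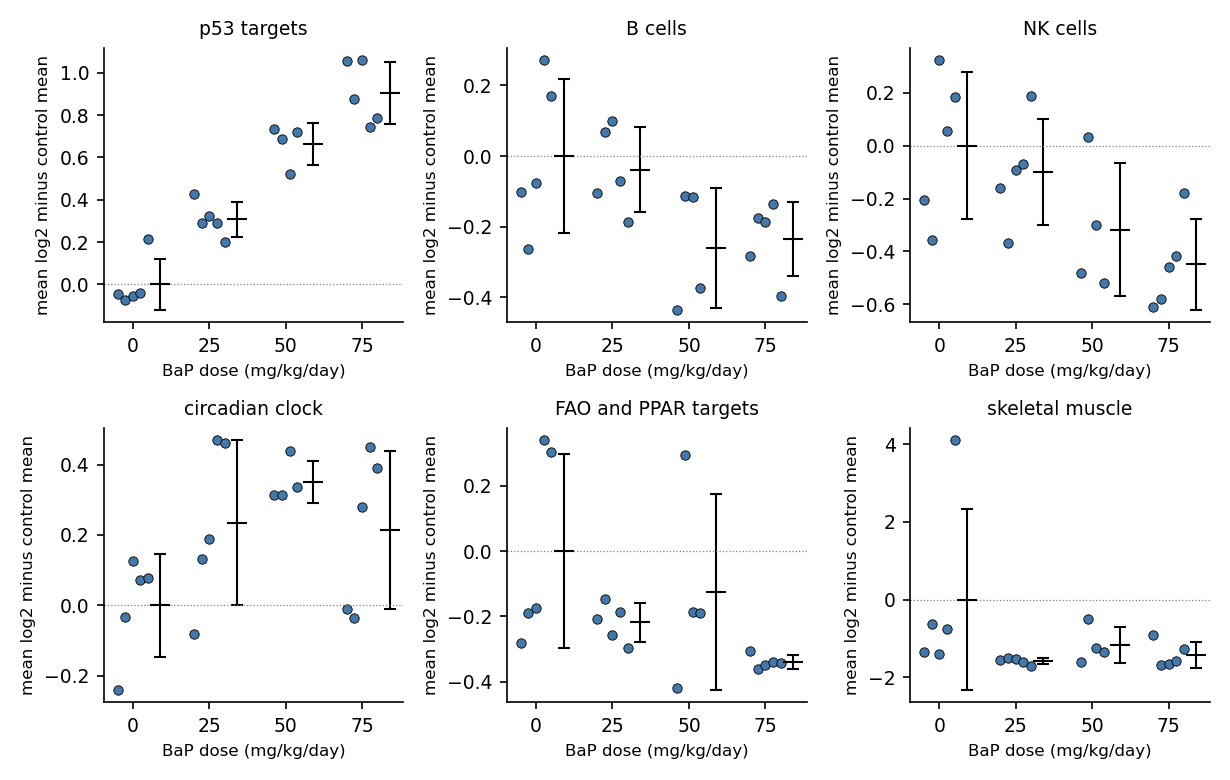
Mean log2 ratio of the genes of a list minus the control mean (y axis) against BaP dose in mg/kg/day (x axis) for p53 targets, B cells, NK cells, the circadian clock, fatty acid oxidation and PPAR targets, and skeletal muscle. Each point is a mouse and the bar beside each group gives the mean and SD (n = 5, 5, 4 and 5). The p53 score was 0.91 ± 0.15 at 75 mg/kg/day, and the skeletal muscle score of control 5 was 4.1.

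Skeletal muscle markers were lower at every dose by camera with its preset correlation (adjusted p = 1.42e-07, 0.00441 and 0.00123). Median log2 differences were -1.58, -1.23 and -1.48 over 11 genes, none of which passed alone. With an estimated correlation the adjusted p was 0.613, 0.897 and 0.729. Control 5 alone had a score of 4.1, against -1.41 to -0.62 in the other controls and -1.7 to -0.499 in the treated mice. Without control 5 the adjusted p was 0.208 at 50 mg/kg/day and 0.078 at 75 mg/kg/day. At 25 mg/kg/day it was at most 3.41e-05 without any 1 mouse. There the 5 treated scores (-1.7 to -1.5) lay below those of all controls (exact permutation p = 0.0079, adjusted over the lists 0.18). The exact permutation p was 0.54 at 50 mg/kg/day and 0.071 at 75 mg/kg/day, where treated scores overlapped those of the controls other than control 5. Cardiac muscle markers were lower at 25 mg/kg/day (adjusted p = 0.000184) and 75 mg/kg/day (0.0442), and adipose markers likewise (7.12e-05 and 0.0469). With an estimated correlation these 4 values were 0.617, 0.729, 0.613 and 0.729 as adjusted p. The cardiac and adipose calls at 75 mg/kg/day ended with slide as a block (adjusted p = 0.129 and 0.148) and without any of controls 4 and 5 and mice 17, 18 and 19 at 75 mg/kg/day or 6 and 9 at 25 mg/kg/day, with an adjusted p of up to 0.202 and 0.256. Ankrd1, on the cardiac list, rose by 1.07 ± 0.28 at 75 mg/kg/day. Genes of fatty acid oxidation and PPAR targets were lower at 25 mg/kg/day (adjusted p = 0.0173) and 75 mg/kg/day (0.00108), where Acot1 fell by 0.91 ± 0.16 and the fatty acid transporter gene Slc27a1 by 0.42 ± 0.12. Fatty acid oxidation gave an adjusted p of 0.644 and 0.729 with an estimated correlation, and muscle and fat markers were lower in the same comparisons. The score of this list was below the control mean in 5 of 5 mice at both doses, and lower on 2 of 4 slides at 25 mg/kg/day and 4 of 4 at 75 mg/kg/day. An exact permutation test of it gave p = 0.21 and 0.0079, and adjusted over the lists 0.52 and 0.13. Slc27a1 was at 0.12 with median centring, below the median of all genes in that setting (0.351). At 25 mg/kg/day the call of the list ended with slide as a block (0.259) and without control 4, where the adjusted p was 0.222, control 5 or mouse 10.

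Other lists were called mostly at the lowest dose, and each of these calls was lost with an estimated correlation. Alveolar type 1 markers were higher at 25 mg/kg/day (adjusted p = 0.00232) and 50 mg/kg/day (0.0269), and in the estimated form the adjusted p was 0.613 and 0.772. Of them Igfbp2 rose 2.1-fold and Hs2st1 1.4-fold at 75 mg/kg/day, where the list was not called (camera adjusted p = 0.0878). Erythroid markers were higher at the 2 lower doses (0.00405 and 0.00121, estimated form 0.613 and 0.63), with Slc4a1, the band 3 anion exchanger, at 0.77 ± 0.26 and 0.83 ± 0.28. Endothelial markers were higher at the 2 lower doses (0.00712 and 0.0352, estimated form 0.617 and 0.772), although Ednrb, on that list, fell at 75 mg/kg/day. Circadian clock genes were higher at the 2 lower doses (0.0275 and 0.00152, estimated form 0.644 and 0.727), with Nr1d1 at 0.78 ± 0.22 and 0.79 ± 0.24 (adjusted p = 0.37 and 0.12) and Nfil3 at -0.44 ± 0.13 and -0.54 ± 0.14 (0.4 and 0.077). Other Nr1d1 probes were at 0.19 and 0.15 at 75 mg/kg/day, against 0.72 for the probe used. With slide as a block the list kept both calls (0.0402 and 0.00134). In that fit Nr1d1, Per2 and Nr1d2 passed alone at 50 mg/kg/day (0.036, 0.033 and 0.041) and Nfil3 did not (0.06). The clock score was higher in 4 of 5 mice at 25 mg/kg/day (exact permutation p = 0.1) and 4 of 4 at 50 mg/kg/day (0.0079, adjusted over the lists 0.13). At 25 mg/kg/day alone, cell cycle genes were higher (adjusted p = 0.0173, estimated form 0.702), and slide as a block ended this call (0.376). Club cells (0.0173), ciliated cells (0.0261), smooth muscle (0.0162), monocytes and macrophages (0.0375), inflammation (0.0173) and cholesterol synthesis (0.0317) were lower, with adjusted p between 0.617 and 0.702 in the estimated form. No member of these lists passed alone at 25 mg/kg/day, and camera called none of the lists at 75 mg/kg/day. The direction of the inflammation list was up at 75 mg/kg/day (camera adjusted p = 0.125), opposite to its call at 25 mg/kg/day. Members of these lists that passed alone at 75 mg/kg/day include Cbr2 (-0.54 ± 0.12), Acta2 (-0.62 ± 0.14), Tnfaip3 (0.48 ± 0.11) and Icam1 (0.66 ± 0.18). Cbr2 and Acta2 were at 0.46 and 0.22 with median centring, above and below the median of all genes there (0.351). Each of the 5 controls and of the 5 mice at 25 mg/kg/day, left out alone, ended at least 1 of the calls at that dose. Without control 4 the adjusted p was 0.931 for monocytes and macrophages, 0.285 for club cells, 0.421 for ciliated cells, 0.0979 for endothelial cells, 0.147 for smooth muscle and 0.324 for inflammation. It was 0.574 for the cell cycle without control 5, 0.177 for cholesterol synthesis without control 2 and 0.182 for the circadian clock without mouse 9. At 50 mg/kg/day it was 0.296 for alveolar type 1 cells and 0.279 for endothelial cells without mouse 15, and slide as a block ended both calls (0.0926 and 0.101). In all, camera called 16, 8 and 8 of the 34 lists at the 3 doses and 6 in the trend. With an estimated correlation it called 1 in each, p53 targets.

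For the remaining lists camera made no call in any comparison. In the trend with dose the adjusted p was 0.494 for the AhR battery, 0.59 for NRF2 and glutathione genes, 0.294 for DNA repair, 0.494 for plasma cells and 0.279 for MHC class II. It was 0.991 for alveolar macrophages, 0.0666 for neutrophils, 0.693 for alveolar type 2 cells, 0.991 for fibroblasts and matrix, 0.0704 for mesothelium and 0.653 for the interferon response. Immediate early genes gave 0.549, heat shock and unfolded protein genes 0.504, glucocorticoid targets 0.224 and other xenobiotic enzymes 0.909. Of 31 DNA repair genes 2 rose at 75 mg/kg/day and 1 fell. They were chosen after their values were seen: Polk, Ercc5 (0.44) and Mutyh (-0.32). Of 26 NRF2 and glutathione genes, 2 rose and 1 fell, also named after their values were seen: Ephx1 rose 2.91-fold, Srxn1 rose by 0.43 and the metallothionein gene Mt1 fell by 0.51.

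The reference channel held the same RNA on every array and should differ between groups only through the measurement, or through the lung channel, since loess and Aquantile use both. At 25 and 50 mg/kg/day limma called 0 genes there (399 and 613 at an unadjusted p under 0.05, against 966 by chance). At 75 mg/kg/day 19 genes were higher in the reference channel, and 14 of them were also called in the ratio. They include the endothelial genes Robo4 (0.78 ± 0.10) and Cldn5 (0.57 ± 0.09) and the ribosomal protein genes Rplp0 (0.44 ± 0.07), Rpl38 (0.33 ± 0.06) and Rps4x (0.32 ± 0.05), all named after their values were seen. The log2 ratios of Rplp0, Rpl38 and Rps4x differed from control by -0.48, -0.68 and -0.66, so part of those differences lies in the reference channel. The count was 272 with slide as a block and 6 with median centring followed by quantile normalization. It was 7, 5 and 12 without mice 16, 18 and 19, and 9, 6, 12 and 9 without controls 1, 2, 3 and 5.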

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

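The tests of scaling and of the label of mouse 20, and of muscle RNA in some samples, were chosen after the result was seen, as were the lists of ribosomal protein, respiratory chain and translation genes. In groups of 4 or 5 mice, 37 values stood far from the others of their group among 504 groups tested, where chance gives about 1 in 20 (25). Mouse 12 at 50 mg/kg/day had 6 of them, control 5 and mouse 20 at 75 mg/kg/day 5 each, and mouse 8 at 25 mg/kg/day 4.

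In mouse 20 at 75 mg/kg/day the log2 ratio was 7.3 for Cyp1a1, against 0.13 to 0.45 in the other mice of that dose, 2.43 for Cyp1b1 (-1.13 to -0.62) and 0.44 for Nqo1 (-1.38 to -1.2). Scaling and background correction are argued against, since the excess of mouse 20 over the next mouse stayed at 2.39 or more for both Cyp1 genes under the settings tried, and so is a control or 25 mg/kg/day mouse under this label, since its p53 score was 0.36 above the highest of those mice. By the bound set in advance, a broad response of the other AhR battery genes is argued against, as 1 of 11, Ahrr, was highest in this mouse. That count left out Cyp1a1, Cyp1b1 and Nqo1, the genes high in this mouse, so it does not argue against an AhR response of these genes. Ahrr, the receptor's repressor, was 1.13 higher on the log2 scale than the mean of the other arrays, or 8.15 of their SDs. An AhR response of part of the battery therefore stays open, as does a swap with a sample from outside these arrays. Of all genes 4.45% were highest in mouse 20. After Cyp1a1 (6.84 above the next mouse of its dose) came Reg3g (3.94), Cyp1b1 (3.04), Ltf (2.82), Cfd (2.7), Bpifb1 (2.66), Car3 (2.47), Apol7c (2.28) and the fat cell genes Fabp4 (2.26) and Adipoq (2.2). Cfd and Car3 are, like Adipoq, on the adipose list. The adipose score was 0.648 in mouse 20, against -1.6 to -0.646 in the other mice of its dose. Controls 4 and 5 and mouse 13 at 50 mg/kg/day had higher adipose scores.

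Ribosomal protein genes were lower at 75 mg/kg/day than in the controls (median -0.47 over 76 genes, 48 of them called lower, exact permutation p = 0.0079, the smallest possible). The median was -0.46 with slide as a block (64 called lower) and -0.27 with Agilent processed signals (37). It was -0.31 in the lung channel alone (17) and -0.17 with deposited values (8). With median centring their median was 0.47. Scaling therefore stays open, although all genes had a median of 0.35 in that setting, so that relative to all genes these were 0.12 higher. Lower readings of short abundant transcripts, as with poor RNA, are argued against in the main ratios at 75 mg/kg/day but not at 25 mg/kg/day. At 25 mg/kg/day the medians of ribosomal and respiratory chain genes were -0.15 and -0.12. At 75 mg/kg/day respiratory chain subunit genes had a median of -0.1. The score of ribosomal protein genes minus that of the subunit genes differed there by -0.33 from the controls (exact permutation p = 0.024). In other settings this score was not tested. The ribosomal and respiratory chain medians at 75 mg/kg/day were -0.31 and -0.08 in the lung channel alone and -0.17 and -0.01 with deposited values. They were 0.47 and 0.67 with median centring. Translation factors and related mRNAs had a median of -0.28 (exact permutation p = 0.0079), but a median of 0.53 with median centring, so a lower level of mRNAs of the translation machinery stays open as well. In the reference channel, which held the same RNA on every array, the ribosomal protein genes had a median of 0.15, against -0.31 in the lung channel. Part of the difference in ratio therefore lies in the reference channel. Loess and Aquantile use both channels, so a technical source and a change carried over from the lung channel are not told apart.

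Skeletal muscle markers set control 5 apart, with a score of 4.1 against -1.41 to -0.62 in the other controls, and Tnnt3 at 6.88 (-0.54 to 0.86) and Mylpf at 5.5 (-0.88 to -0.28). The SD of the score between mice of a group reached 2.32, in the controls, which restates the value of control 5 and is no further support, so muscle RNA in some lung samples stays open. With muscle and fat scores as covariates the median of fatty acid oxidation genes at 75 mg/kg/day went from -0.26 to -0.05 on the log2 scale, so muscle and fat content may account for that difference. An effect of BaP on fat or muscle in the tissue taken was not tested apart from this and stays open.

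Other values of muscle and fat markers stood apart. In mouse 12 at 50 mg/kg/day Sln was at 0.01 (others 4.72 to 5.67) and Myl7 at 0.66 (5.62 to 6.51). Actc1 was at 1.14 in mouse 20 at 75 mg/kg/day (-1.49 to -0.9), and Mylpf at -0.89 in mouse 8 at 25 mg/kg/day (-0.7 to -0.68), whose adipose score was -0.43 (-1.69 to -1.34). Mouse 13 at 50 mg/kg/day had Lipe at 1.15 (0.65 to 0.7) and Cpt1b at 1.47 (0.36 to 0.4).

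Among the genes changed with dose, Cdkn1a was at 0.86 in mouse 14 at 50 mg/kg/day (1.35 to 1.45) and Phlda3 at 2.62 in mouse 16 at 75 mg/kg/day (2.22 to 2.27). Mouse 12 at 50 mg/kg/day had Thyn1 at 0.7 (-0.29 to -0.14), Rps13 at -1.33 (-0.75 to -0.65) and Aldh1a7 at 4.54 (4.92 to 4.94). Grp was at 2.29 in control 5 (1.35 to 1.6), whose p53 score was 0.22 (-0.08 to -0.04). Tmeff2 was at 0.79 in control 1 (1.47 to 1.57) and at 1.2 in mouse 19 at 75 mg/kg/day (-0.06 to 0.11), Acot1 at 1.39 in control 3 (1.99 to 2.16), Rps13 at -0.7 in control 1 (-0.12 to 0.04) and Lars2 at 2.05 in mouse 6 at 25 mg/kg/day (1.48 to 1.61).

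Among list members, control 4 had Hs2st1 at 0.69 (1.01 to 1.12), Pecam1 at 2.22 (2.79 to 2.93) and Saa3 at 0.21 (-3.05 to -2.27), and control 2 had Tspo2 at -0.02 (0.28 to 0.37). Mouse 9 at 25 mg/kg/day had Pecam1 at 2.56 (3 to 3.17) and Stard4 at 0.55 (0.09 to 0.18), and mouse 8 at that dose Fcgr3 at 2.1 (1.11 to 1.22) and Cyp1b1 at -0.57 (-1.07 to -0.96). Stard4 was at -0.13 in mouse 19 at 75 mg/kg/day (0.14 to 0.18) and Lck at -0.46 in mouse 17 at 75 mg/kg/day (-0.9 to -0.82). The lung channel of mouse 12 had 19790 spots well above background (24301 to 25139), and the reference channel of mouse 20 had 30954 (26048 to 26827).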

How the results depend on the processing

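The fits without the 4 arrays marked for evaluation, those with muscle and fat scores as covariates and the exact permutation of list scores were chosen after the data were seen. The p53 targets kept their call in 30 of 30 alternatives run with camera or fry at each dose and in the trend, and Cdkn1a, Gdf15 and Phlda3 kept theirs at 50 and 75 mg/kg/day in 39 of 39. The cause of the changes below was not tested unless given. Dim lung signals, with a median of 11.7 to 36.6 units above background per array, limit what small changes can be seen.

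With median centring 0, 9 and 535 genes were called at 25, 50 and 75 mg/kg/day, the last as 532 higher and 3 lower, and 15 lists at 75 mg/kg/day and 11 in the trend. The trend count was 1020, with 1012 rising and 8 falling. Of 80 called values of named genes 25 kept their call in this setting, 47 lost it and 8 reversed at 75 mg/kg/day: Rps27 0.37, Rpl13 0.26, Lars2 0.12, Cbr2 0.46, Acta2 0.22, Slc27a1 0.12, Cd79b 0.11 and Blnk 0.18. All genes had a median of 0.35 at that dose in this setting, so these signs follow a shift common to all genes, and only Rps27 and Cbr2 lay above that median. Agilent processed signals gave 36 genes, all higher, at 25 mg/kg/day, 1449 at 75 mg/kg/day, 0 between 25 and 50, 1 between 50 and 75, 1606 in the trend and 179 in the trend of treated mice, 14 lists at 75 mg/kg/day and 11 in the trend. The endothelial list at 25 mg/kg/day reversed there (adjusted p = 0.705). Scaling between arrays gave 4 and 88 genes at 25 and 50 mg/kg/day.

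The lung channel alone gave 4 genes at 25 mg/kg/day and 100 at 50, 1 between 25 and 50 and 67 between 25 and 75, and at 75 mg/kg/day 473 higher and 150 lower. Deposited values, and the fit without the dim-probe filter, gave 0 genes between 25 and 50 mg/kg/day. Fits of only the groups compared, which hold fewer arrays, gave 5, 51 and 422. With slide as a block there were 413 and 1776 genes at 50 and 75 mg/kg/day, 1 between 25 and 50, 293 between 25 and 75, 1745 in the trend, 309 in the trend of treated mice and 272 in the reference channel. With slide as a random block there were 41, 634 and 1846 genes at the 3 doses, 298 between 25 and 75, and 1837 and 348 in the trends. With scan day as a block there were 19, 337 and 1491, and 1500 in the trend.

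Stricter thresholds call fewer genes by construction: with at least 1.5-fold as well, 6, 98 and 271 and 272 in the trend, and at an adjusted p under 0.01, 3, 69 and 320 and 399 in the trend. Without the 4 arrays marked for evaluation 3 and 96 genes were called at 25 and 50 mg/kg/day, 0 between them, 197 between 25 and 75, 236 in the trend of treated mice and 13 lists at 75 mg/kg/day. With muscle and fat covariates 0 and 87 genes were called at 25 and 50 mg/kg/day, 0 between them and 30 in the trend of treated mice. The count of 0 at 25 mg/kg/day is a loss of calls. Over all alternatives Cdkn1a, Gdf15 and Phlda3 stayed at least 1.22, 1.14 and 0.91 higher on the log2 scale at that dose. Matn2 and Ephb2 came as near to control as -0.31 and -0.26. An estimated correlation called 1 list in each comparison, fry 1 at each dose and 2 in the trend, and exact permutation 0 at each dose, where a single list at the smallest possible p cannot pass. With the controls divided, the agreement r was 0.173, 0.296 and 0.305. Median centring followed by quantile normalization called 6 reference channel genes.

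Leaving out 1 mouse at a time gave 3 to 13 genes at 25 mg/kg/day, 77 to 216 at 50 and 454 to 980 at 75, 0 to 4 between 25 and 50, 0 to 0 between 50 and 75 and 49 to 121 between 25 and 75. The trend had 589 to 1043 genes and that of treated mice 51 to 148. List counts were 7 to 17, 6 to 11 and 5 to 12 at the 3 doses and 6 to 10 in the trend, and the reference channel had 5 to 23. Lists fell to 7 at 25 mg/kg/day without control 4 and to 5 at 75 mg/kg/day without mouse 18 or control 5, and in the trend they were 10 without control 4. Cyp1a1 at 75 mg/kg/day ranged from -1.16 (adjusted p = 0.023), without mouse 20, to 0.63.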

Other observations

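The counts of splits were planned before the result was seen, and the members named here and the fit with muscle and fat scores as covariates were chosen after the values were seen. Some list members passed alone although their list did not. At 75 mg/kg/day the plasma cell regulator gene Prdm1 rose by 0.65 and Fkbp11 by 0.56, Csf3r, the receptor for the granulocyte growth factor, rose by 0.51, and Ccn1, a matricellular protein gene, rose by 0.91. Klf2, a transcription factor of quiescent endothelium, fell by 0.53, the keratin genes Krt8 and Krt18 fell by 0.53 and by 0.49, and the fibroblast receptor gene Pdgfra fell by 0.42. Trib3 fell by 0.45 and Cyp2j6 rose by 0.45.

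Other splits of the same arrays, 100 per comparison with the real one included, gave counts to set beside the real ones. As many genes were called by 2 splits at 25 mg/kg/day (10 in the real split, 178 in the highest other), 2 at 50 mg/kg/day (211 and 345) and 1 at 75 mg/kg/day (807 and 416). The smallest share that 100 splits can give is 1 of 100, so chance alone is unlikely for the count at 75 mg/kg/day. With 2 of 100 splits, chance is also unlikely at 25 and 50 mg/kg/day, and it is not excluded at any dose. The splits exchange arrays freely across slides and do not test slide, and at each of 25 and 50 mg/kg/day 1 split gave more genes than the real one, so there a structure of the arrays is not excluded. No other split gave as many between 25 and 75 mg/kg/day (1 split, 110 and 1) or for the trend (1 split, 900 and 1). The same held for the trend of treated mice (1 split, 113 and 21) and for the reference channel at 75 mg/kg/day (1 split, 19 and 0). Chance is unlikely for these counts as well. Between 25 and 50 mg/kg/day 1 split gave as many (2 genes and 1), but neither this count nor that of 10 genes at 25 mg/kg/day settles it. With muscle and fat scores as covariates both counts were 0, which is a loss of calls. Over all alternatives, that fit included, Cdkn1a stayed between 1.22 and 1.56 higher on the log2 scale at 25 mg/kg/day and Gdf15 between 1.14 and 1.72. Between 50 and 75 mg/kg/day the real count was 0, so that all 100 splits gave as many by construction (highest other 10) and this says nothing about chance. For the numbers of lists chance cannot be excluded: 16 splits gave as many at 25 mg/kg/day (16 and 21), 67 at 50 mg/kg/day (8 and 23), 76 at 75 mg/kg/day (8 and 21) and 82 in the trend (6 and 25).

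At 25 mg/kg/day the highest other split points to a structure of the arrays: with 178 genes it parts the arrays of slides 1, 3 and 5 from those of slides 2, 4 and 6. The split with 345 genes at 50 mg/kg/day sets controls 1, 2 and 3 and mouse 12 against the others, with both arrays of slide 5 on one side and both of slide 6 on the other, while slide 1 is divided. These arrays had 19777 to 22300 lung spots well above background, against 24301 to 26034 in the others of the 2 groups. Controls 1 and 3 and mouse 12 were marked for evaluation. The split also keeps 3 of 5 controls and 3 of 4 treated mice together, so slide, lung signal and the dose difference that remains are not told apart. No array at 75 mg/kg/day had fewer than 23548 such spots, so lung signal was not balanced over the doses. With slide as a block 14, 413 and 1776 genes were called at the 3 doses. The split with 416 genes at 75 mg/kg/day exchanges only control 3 and mouse 20, both among the arrays marked for evaluation, so most of the dose difference remains in it and it does not show a structure of the arrays.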
